A study of Mus musculus with 12 samples.

How the data were processed

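RNA sequencing was done on long-term haematopoietic stem cells (LT-HSCs, the bone marrow cells that sustain blood formation over a lifetime) from wild-type mice and from mice labelled Trim47-/-. Mice were untreated or had received 5-fluorouracil (5-FU), a drug that kills cycling cells, with 10 days given in the labels. The labels place 3 libraries in each of 4 groups, and the groups and replicate numbers were taken from the sample titles. The surface markers of the LT-HSC gate and the part of Trim47 that was deleted are not given in the sources used here. Per the labels' protocols, poly-A RNA was made into paired-end libraries with a stranded mRNA kit and sequenced on an Illumina NovaSeq.

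The deposited table gives, for each of the 12 libraries, a whole-number count per gene, which is not normalised. The submitters' processing notes name CASAVA 1.8, HISAT2, StringTie and edgeR with the genome build GRCm38, without saying which tool did which step. The tool that made the counts, its strand setting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner may not be told apart. Genes with near-identical copies, such as the globins, Amd1 with Amd2, the Lilr4b family and ribosomal protein genes with their pseudogenes, carry the same uncertainty. Per the file headers, the table also holds FPKM values. The count divided by the FPKM gave 1 fixed length per gene once scaled by the library total, with a largest deviation of 0.00108% over 11212 genes with at least 50 counts in each library, so the FPKM added no separate measurement and was not used in the tests. Of 28999 genes in the table, 28923 identifiers were found in the GENCODE M21 annotation of GRCm38, 28696 with the same coordinates, and 51 symbols stood for more than 1 identifier.

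Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, edgeR's default filter on low counts over the 4 groups, which kept 16319 genes, and the quasi-likelihood test. All 12 libraries entered 1 fit with 1 mean per group, so the groups shared an estimate of the spread. The comparisons were Trim47-/- against wild type in untreated mice and after 5-FU, 5-FU against untreated in each genotype, and the interaction, which is the 5-FU response in libraries labelled Trim47-/- minus that in wild type. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, counts scaled to TMM-adjusted library size, given as mean ± SD over the 3 libraries of a group. Log2 fold changes come from the fit, with a standard error (SE).

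Before the data were examined, 30 gene lists were fixed for pathways of stem cells, cell cycle, stress, innate signalling and metabolism, for markers of other blood and marrow cells that the gate could hold, and as checks of sex and of the Trim47 locus. Of these, 29 were tested with limma's camera (limma 3.58.1) with its preset correlation between genes of 0.01, adjusted over the 29 lists in each comparison. The sex-linked list, with fewer than 5 measured members, was not tested. The rule for named genes was also fixed: Trim47, and per comparison the 6 rising and 6 falling genes with the largest change among those that passed, had a mean of at least 10 CPM over the 6 libraries compared, and had all 3 libraries of one group above all 3 of the other. For the interaction the mean was taken over all 12 libraries, and no separation of groups was required. Gene models named Gm or ending in Rik and immunoglobulin or T-cell receptor segments were left out of that rule. For each list described, up to 4 members with the smallest p were named. The median log2 change of each list was also set against 10000 random lists of as many genes with like mean levels. The share of random lists with a lower median is given for called lists whose median lay nearest theirs. Some genes that these rules select are not reported. Sets of passing genes were compared with two-sided Fisher's exact tests, and the comparisons set side by side in this way share no libraries.

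The alternatives fixed in advance were DESeq2's size factors in edgeR, the DESeq2 1.42.0 test, no filter on low counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0), only the 6 libraries compared, a 2-fold threshold, an adjusted p under 0.01, camera with an estimated correlation, and each library left out in turn. A test against a 1.5-fold change, a restriction to genes whose libraries lay within 1.5-fold in every group, libraries summed by group without a test, and the overlap of the 5-FU responses were added after seeing the data. Numbers were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

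The procedure was tested on simulated counts drawn from the real means, library sizes and spread between libraries of a group. Each gene had 1 mean over all groups, except 200 genes changed by known folds, 50 per fold, and 30 others shifted by 0.3 in log2. It recovered 78% of 2-fold changes in untreated mice between genotypes (16003 genes tested), 80% after 5-FU (16026), 76% for 5-FU in wild type (16014), 70% for 5-FU in Trim47-/- (15994) and 58% for the interaction (15997). For 1.25-fold changes the shares were 24%, 22%, 14%, 26% and 8% in the same order. Between 3 and 16 unchanged genes were called per comparison. These values hold for a spread like that between these libraries, which may be technical, and for far fewer changed genes than passed in the real data. Total counts per library ran from 13919649 to 20703198, so 3 counts, the limit that a count of 0 allows, corresponded to 0.145 to 0.216 CPM. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.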

Results

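The data set held 12 RNA-seq libraries of mouse bone marrow cells labelled LT-HSCs, 3 for each of 4 groups. The groups were wild type untreated, Trim47-/- untreated, wild type after 5-FU and Trim47-/- after 5-FU. Trim47 encodes a tripartite-motif protein of the E3 ubiquitin ligase type. The design asks which genes differ with the Trim47 genotype in LT-HSCs at rest and after 5-FU, and whether the response to the drug differs with genotype. Total counts ran from 14828152 to 14885673 in untreated wild type and from 20661120 to 20703198 in untreated Trim47-/-. After 5-FU they ran from 15111811 to 15151589 in wild type and from 13919649 to 13953510 in Trim47-/-. All 12 libraries held RNA of the Y-linked gene Ddx3y (93.4 to 180 CPM) and little of the X-inactivation transcript Xist (0 to 0.337 CPM). Mitochondrial messenger RNA made up 2.42%, 2.68%, 2.49% and 2.63% of counts in the order of groups above (means, n = 3 each), and mitochondrial ribosomal RNA 0.168%, 0.159%, 0.216% and 0.248%. Long noncoding RNA of the intergenic and antisense types took 0.574%, 0.489%, 0.445% and 0.364%, and pseudogenes 8.26%, 8.57%, 8.92% and 9.43%. In total counts and in these shares of RNA types, the ranges of no groups overlapped, while those of Ddx3y and Xist did between some groups. Whether RNA quality or its preparation differed with the groups was not tested, so it stays open as a part of the changes below.

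The labels name no separate animals behind the libraries. The p-values of single genes measure only the spread between these libraries, which may be technical. Those of gene lists and of overlaps compare sets of genes, which are not independent replicates. Within a group, genes with 1 transcript and no overlapping gene had a median chi-square per degree of freedom of 0.746 to 0.800, against 0.693 under counting noise alone. Over all genes the median was 1.03 to 1.10, and 12.6% to 13.9% of genes lay beyond counting noise where chance gives 1%. Among genes with 5 or more transcripts that share was 18.3% to 20.3%. The use of 165 immunoglobulin V segments, which differs from animal to animal, correlated across segments at r = 0.968 to 0.994 within groups (12 pairs of libraries). Between groups it correlated at 0.536 to 0.699 (54 pairs). The number of genes that changed at least 2-fold is given beside each count. A fold threshold cannot tell a difference between single RNA sources from an effect of genotype or drug.

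Trim47 RNA was present in every library. Its level was 24.4 ± 0.531 CPM in untreated wild type and 19.7 ± 3.63 CPM in untreated libraries labelled Trim47-/- (SD, n = 3 each). Single libraries stood at 24.6, 23.8 and 24.7 CPM against 23.7, 18.9 and 16.6 CPM. That difference, log2 -0.31 (SE 0.115, adjusted p = 0.0632), did not pass in edgeR's test. Without untreated Trim47-/- replicate 1 it did, at -0.45 and adjusted p = 0.0046 (0.0046 to 0.211 over its alternatives). After 5-FU, Trim47 stood at 35.4 ± 2.5 CPM in wild type and 11.3 ± 1.09 CPM in libraries labelled Trim47-/-, a log2 difference of -1.64 (SE 0.121, adjusted p = 5.50e-07). Trim47 (ENSMUSG00000020773) lies on chromosome 11 at 116105752 to 116127210 of GRCm38, minus strand. It overlaps its neighbour Trim65 (116121846 to 116131128) on the same strand, so reads could be split between both. Trim65 stood at 20.6 ± 1.19 CPM in untreated wild type and 24.9 ± 1.96 CPM in untreated Trim47-/-, log2 0.27 (SE 0.095, adjusted p = 0.0466). It gained nearly as many CPM as Trim47 lost, so the untreated difference in Trim47 may come from how reads were divided between the pair. After 5-FU Trim65 fell as Trim47 did, from 23.6 ± 1.61 to 15.5 ± 2.04 CPM, log2 -0.61 (SE 0.0982, adjusted p = 0.000289). Since the deleted part is not given and counts are per gene, these levels do not fully check the genotype, and the groups are named as labelled throughout. Among 15 measured genes at and around the locus, 4 rose and 2 fell (4 and 3 adjusted over the list alone) in untreated mice (adjusted p = 0.6 for the list). After 5-FU, 4 rose and 7 fell (4 and 7 adjusted over the list alone), with adjusted p = 0.435. Adjusted p-values of lists are those of camera with its preset correlation. With an estimated correlation those of called lists were higher. These are given for lists that lost their call and for some that kept it.

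**Figure D1:**
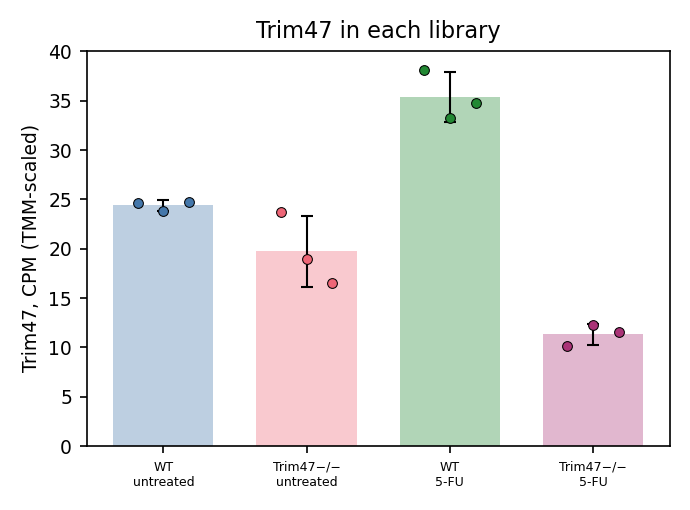
Trim47 in each library, in TMM-scaled CPM (y axis) by group (x axis), with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. The libraries labelled Trim47-/- held between 10.1 and 23.7 CPM.

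In untreated mice, NF-kB target genes and monocyte genes were lower in LT-HSC libraries labelled Trim47-/- than in wild type, while erythroid and LT-HSC genes were higher. Acod1, which makes itaconate in activated myeloid cells, went from 28.6 ± 1.19 CPM in wild type to 7.33 ± 0.742 CPM (SD, n = 3 each). It changed by -1.96 (SE 0.104, adjusted p = 1.22e-07) on the log2 scale, which is used for every change. Errfi1, an inhibitor of the EGF receptor, changed by -1.77 (SE 0.0846) and Clec4e, the receptor Mincle, by -1.73 (SE 0.0964). Lilr4b, of an inhibitory receptor family with near-identical members, changed by -1.66 (SE 0.118). Kcnq1ot1, a non-coding RNA antisense to Kcnq1, changed by -1.91 (SE 0.0889). Largest changes are ranked here, and in each pairwise comparison, among genes with a mean of at least 10 CPM and groups that do not overlap. For the interaction no separation of groups was required. Among the largest rises were those of Zscan2 (1.34, SE 0.262), Sema3d (1.13, SE 0.0709), Gprc5b (1.09, SE 0.084) and Rasa3, a GTPase-activating protein (1.07, SE 0.186). Eps8l1 rose from 16.3 ± 1.08 to 40.2 ± 1.49 CPM (adjusted p = 2.26e-07). Lrrc8d, a subunit of a volume-regulated anion channel, was higher by 2.15 (SE 0.674, adjusted p = 0.0299). It stood at 12.3 ± 1.25 CPM in untreated wild type and 54.7 ± 11 CPM in untreated Trim47-/-. Over all 4 groups its replicates lay up to 6.59-fold apart. It lost its call without each of the 3 wild-type libraries (adjusted p = 0.0778, 0.0731 and 0.087) and without Trim47-/- replicates 2 and 3 (0.0674 and 0.0652), with a range of 0.000156 to 0.087 over its alternatives. In edgeR's quasi-likelihood test 5392 of 16319 genes passed, 2873 higher and 2519 lower in Trim47-/-. That balance turned with DESeq2 size factors (2567 higher, 2717 lower), with the DESeq2 test (1988 and 2333) and with only the 6 libraries compared (2324 and 2712). Of the 5392 genes, 612 changed at least 2-fold (121 higher, 491 lower), and 3391 passed at an adjusted p under 0.01.

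Of 32 NF-kB targets, 1 rose, 27 fell and 4 did not pass (1 and 28 adjusted over the list alone), and 7 fell at least 2-fold. The median was -0.56 (adjusted p = 3.97e-18, and 0.000187 with an estimated correlation). Those that fell included Cd83 (-1.23), the adhesion molecule Icam1 (-0.80), the chemokine Cxcl2 (-0.94) and the subunit gene Nfkb2 (-0.57). Of 46 type I interferon response genes, 7 rose, 21 fell and 18 did not pass (8 and 21 adjusted over the list alone, median -0.17, adjusted p = 0.00249). With an estimated correlation the interferon list had adjusted p = 0.0456. Irf7 changed by -0.81 and Bst2 by -0.53. Of 25 genes of the unfolded protein response, 5 rose, 13 fell and 7 did not pass (5 and 13 adjusted over the list alone, median -0.15, adjusted p = 0.00526). This list had adjusted p = 0.0562 with an estimated correlation (0.00322 to 0.0562 over its alternatives). Ddit3, the transcription factor CHOP, changed by -0.86, while the chaperone Hspa5 rose by 0.20. Of 35 LT-HSC identity genes, 16 rose, 2 fell and 17 did not pass (17 and 3 adjusted over the list alone, median 0.23, adjusted p = 0.00605). With an estimated correlation the LT-HSC list had adjusted p = 0.0406. Robo4 (0.61) and Eya2 (0.45) rose, and Tgm2 (-0.60) fell. Of 13 mitochondrially encoded genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), mt-Cytb by 0.23. The median was 0.14 (adjusted p = 4.18e-05), but adjusted p = 0.138 with an estimated correlation (4.60e-05 to 0.138 over its alternatives). Of 35 G1/S and DNA replication genes, 12 rose, 2 fell and 21 did not pass (13 and 2 adjusted over the list alone), Mcm2 by 0.18 (median 0.08, adjusted p = 0.0254). That call was lost with only the 6 libraries compared (0.0925), and the list had adjusted p = 0.17 with an estimated correlation (0.02 to 0.17 over its alternatives).

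Markers of other cell types also differed between the untreated groups. Of 15 monocyte and macrophage genes, 0 rose, 7 fell and 8 did not pass (0 and 9 adjusted over the list alone, median -0.67, adjusted p = 4.18e-05). They included F13a1 (-0.92), Ms4a6c (-0.96) and Csf1r, the M-CSF receptor (-0.67). Of 12 dendritic cell genes, 1 rose, 7 fell and 4 did not pass (1 and 9 adjusted over the list alone, median -0.60, adjusted p = 0.00526). With an estimated correlation the dendritic cell list had adjusted p = 0.0456. Flt3 (0.36) was higher and Bst2 (-0.53) and Clec9a (-2.98) lower. Of 16 megakaryocyte and platelet genes, 1 rose, 11 fell and 4 did not pass (1 and 11 adjusted over the list alone, median -0.51, adjusted p = 0.000107). The platelet chemokine Ppbp stood at 6.87 CPM in wild type and 0.735 CPM in Trim47-/-. Of 17 erythroid genes, 12 rose, 1 fell and 4 did not pass (12 and 1 adjusted over the list alone, median 0.40, adjusted p = 4.18e-05). Hba-a1 rose by 0.81 and the erythrocyte anion exchanger Slc4a1 by 0.91. Of 15 genes of multipotent progenitors and lymphoid priming, 8 rose, 1 fell and 6 did not pass (9 and 2 adjusted over the list alone, median 0.21, adjusted p = 0.015). The list had adjusted p = 0.0562 with an estimated correlation (0.0119 to 0.0562 over its alternatives). Dntt, the terminal transferase of early lymphoid cells, rose by 0.63. Of 18 neutrophil genes, 9 rose, 3 fell and 6 did not pass (9 and 3 adjusted over the list alone, median 0.20, adjusted p = 0.0201), but adjusted p = 0.0562 with an estimated correlation (0.0152 to 0.0562 over its alternatives). Ngp (0.51) and Ltf (0.70) rose while Ctsg (-0.55) fell. Of 12 endothelial and stromal genes, 6 rose, 0 fell and 6 did not pass (6 and 0 adjusted over the list alone, median 0.61, adjusted p = 0.015), but adjusted p = 0.0562 with an estimated correlation (0.00859 to 0.0562 over its alternatives). Emcn rose by 0.67.

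After 5-FU, LT-HSC genes and immediate early genes were lower in libraries labelled Trim47-/- than in wild type, and neutrophil, monocyte, DNA replication and respiratory chain genes were higher. Of 35 LT-HSC identity genes, 3 rose, 28 fell and 4 did not pass (3 and 28 adjusted over the list alone), 15 of them by at least 2-fold. The median was -0.84 (adjusted p = 1.22e-07). Gimap6 went from 217 ± 3.29 to 110.1 ± 1.58 CPM (SD, n = 3 each) and Kit, the stem cell factor receptor, from 459 ± 3.56 to 302 ± 7.08 CPM. Ifitm3, which interferon also induces, rose by 0.70 (SE 0.0244). Of 30 immediate early and dissociation stress genes, 4 rose, 24 fell and 2 did not pass (4 and 25 adjusted over the list alone), 9 by at least 2-fold (median -0.61, adjusted p = 5.07e-09). The AP-1 subunit Fos stood at 2999 ± 8.57 CPM in wild type and 768 ± 7.24 CPM in Trim47-/-, log2 -1.97 (SE 0.0137, adjusted p = 1.52e-15). Jun, its partner, changed by -1.02 (SE 0.00802). Zfp36, which promotes decay of inflammatory messenger RNAs, changed by -1.75 (SE 0.0102) and Dusp1, a phosphatase of MAP kinases, by -1.99 (SE 0.0224). Other large falls were in Gimap8 (-2.23, SE 0.0828), Gdf15, a secreted factor of the TGF-beta family (-2.04, SE 0.0748), and Zbtb4 (-1.75, SE 0.419). Replicates of Zbtb4 lay up to 8.79-fold apart. Apart from Amd1, the largest rises among genes that met this rule were in Acod1 (2.93, SE 0.122), Nlrp3, the sensor of an inflammasome (2.45, SE 0.0995), Lgals3, galectin-3 (2.43, SE 0.148), the protease Mmp19 (2.24, SE 0.194) and Noct, nocturnin (2.18, SE 0.116). Nlrp3 reached 121 ± 15.8 CPM against 22.2 ± 2.14 CPM. Amd1, of polyamine synthesis, was higher by 2.84 (SE 0.888, adjusted p = 0.0181). It stood at 7.82 ± 0.655 CPM in wild type and 55.98 ± 32.8 CPM in Trim47-/- after 5-FU. Over all 4 groups its replicates lay up to 10.3-fold apart. It lost its call without wild-type replicate 1 or 2 or Trim47-/- replicate 3 (adjusted p = 0.0548, 0.0529 and 0.0503), with a range of 0.00308 to 0.0548 over its alternatives. In edgeR's test 8933 genes passed, 4434 higher and 4499 lower in Trim47-/-, and 1434 changed at least 2-fold (551 higher, 883 lower). That balance turned with the replicate block (4384 higher, 4377 lower), the surrogate variable (4242 and 4231) and an adjusted p under 0.01 (3507 and 3417), and without most single libraries.

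Of 35 G1/S and DNA replication genes, 31 rose, 0 fell and 4 did not pass (31 and 0 adjusted over the list alone, median 0.28, adjusted p = 5.07e-09). Mcm5 rose by 0.47, Mcm7 by 0.44 and Pcna by 0.31. Of 35 G2/M genes, 6 rose, 20 fell and 9 did not pass (6 and 20 adjusted over the list alone, median -0.16, adjusted p = 0.012), but adjusted p = 0.0575 with an estimated correlation (0.0105 to 0.0575 over its alternatives). Hmmr (-0.69) and Plk1 (-0.62) were lower and the proliferation marker Mki67 (0.31) was higher. Of 22 CDK inhibitors and quiescence regulators, 3 rose, 13 fell and 6 did not pass (3 and 13 adjusted over the list alone, median -0.33, adjusted p = 0.012). The repressor Gfi1 (-0.94), Rbl2, a relative of the retinoblastoma protein (-0.70), and the antiproliferative gene Btg1 (-0.32) fell, and Tgfb1 (0.30) rose. Of 74 nuclear genes of oxidative phosphorylation, 45 rose, 0 fell and 29 did not pass (45 and 0 adjusted over the list alone, median 0.24, adjusted p = 2.13e-07). Atp5b rose by 0.35 and Ndufb7 by 0.53. Of 13 mitochondrially encoded genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), mt-Nd1 by 0.34. The median was 0.18 (adjusted p = 5.74e-05), but adjusted p = 0.117 with an estimated correlation (3.55e-05 to 0.117 over its alternatives). A lower median was found in 74.5% of random lists, so this list did not stand out by its median. Of 25 unfolded protein response genes, 22 rose, 1 fell and 2 did not pass (22 and 1 adjusted over the list alone, median 0.46, adjusted p = 1.24e-07). They included calreticulin, Calr (0.58), and the transcription factor Xbp1 (0.72). Of 79 cytosolic ribosomal protein genes, 49 rose, 2 fell and 28 did not pass (51 and 2 adjusted over the list alone, median 0.14, adjusted p = 1.18e-05), and Rpl8 rose by 0.30. A lower median was found in 81.1% of random lists, so the ribosomal list did not stand out by its median. Of 32 NF-kB targets, 16 rose, 9 fell and 7 did not pass (16 and 9 adjusted over the list alone, median 0.29, adjusted p = 0.0259), but adjusted p = 0.0557 with an estimated correlation (0.018 to 0.0557 over its alternatives). Rel (1.34), Nfkb2 (1.09) and Cd83 (1.91) rose and Ier3 (-1.43) fell.

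Markers of other cells moved apart after 5-FU. Of 18 neutrophil and granule genes, 14 rose, 2 fell and 2 did not pass (14 and 2 adjusted over the list alone, median 0.67, adjusted p = 1.35e-05). Ltf, lactoferrin, stood at 85.8 ± 5.89 CPM in wild type and 189.6 ± 3.29 CPM in Trim47-/-, and Ngp changed by 0.91, Ctsg by 0.76 and Prtn3 by 0.51. Of 15 monocyte and macrophage genes, 11 rose, 0 fell and 4 did not pass (11 and 0 adjusted over the list alone), 6 by at least 2-fold (median 0.93, adjusted p = 0.000427). F13a1 (1.29), Csf1r (1.23) and Ly86 (1.62) were among them. Of 17 erythroid genes, 1 rose, 10 fell and 6 did not pass (1 and 13 adjusted over the list alone, median -0.27, adjusted p = 0.011), and the carbonic anhydrase Car2 changed by -0.84. A lower median than that of the erythroid list was found in 6.94% of random lists. Of 16 megakaryocyte and platelet genes, 1 rose, 13 fell and 2 did not pass (1 and 13 adjusted over the list alone, median -0.38, adjusted p = 0.00175), and P-selectin, Selp, changed by -0.76. Of 15 multipotent progenitor and lymphoid genes, 3 rose, 11 fell and 1 did not pass (3 and 11 adjusted over the list alone, median -0.31, adjusted p = 0.0237), but adjusted p = 0.0575 with an estimated correlation (0.018 to 0.0575 over its alternatives). Dntt changed by -1.00, while Mn1 rose by 1.69. Of 12 endothelial and stromal genes, 0 rose, 6 fell and 6 did not pass (0 and 6 adjusted over the list alone, median -0.52, adjusted p = 0.0237), but adjusted p = 0.0575 with an estimated correlation (0.0148 to 0.0575 over its alternatives). Emcn changed by -1.18.

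**Figure D2:**
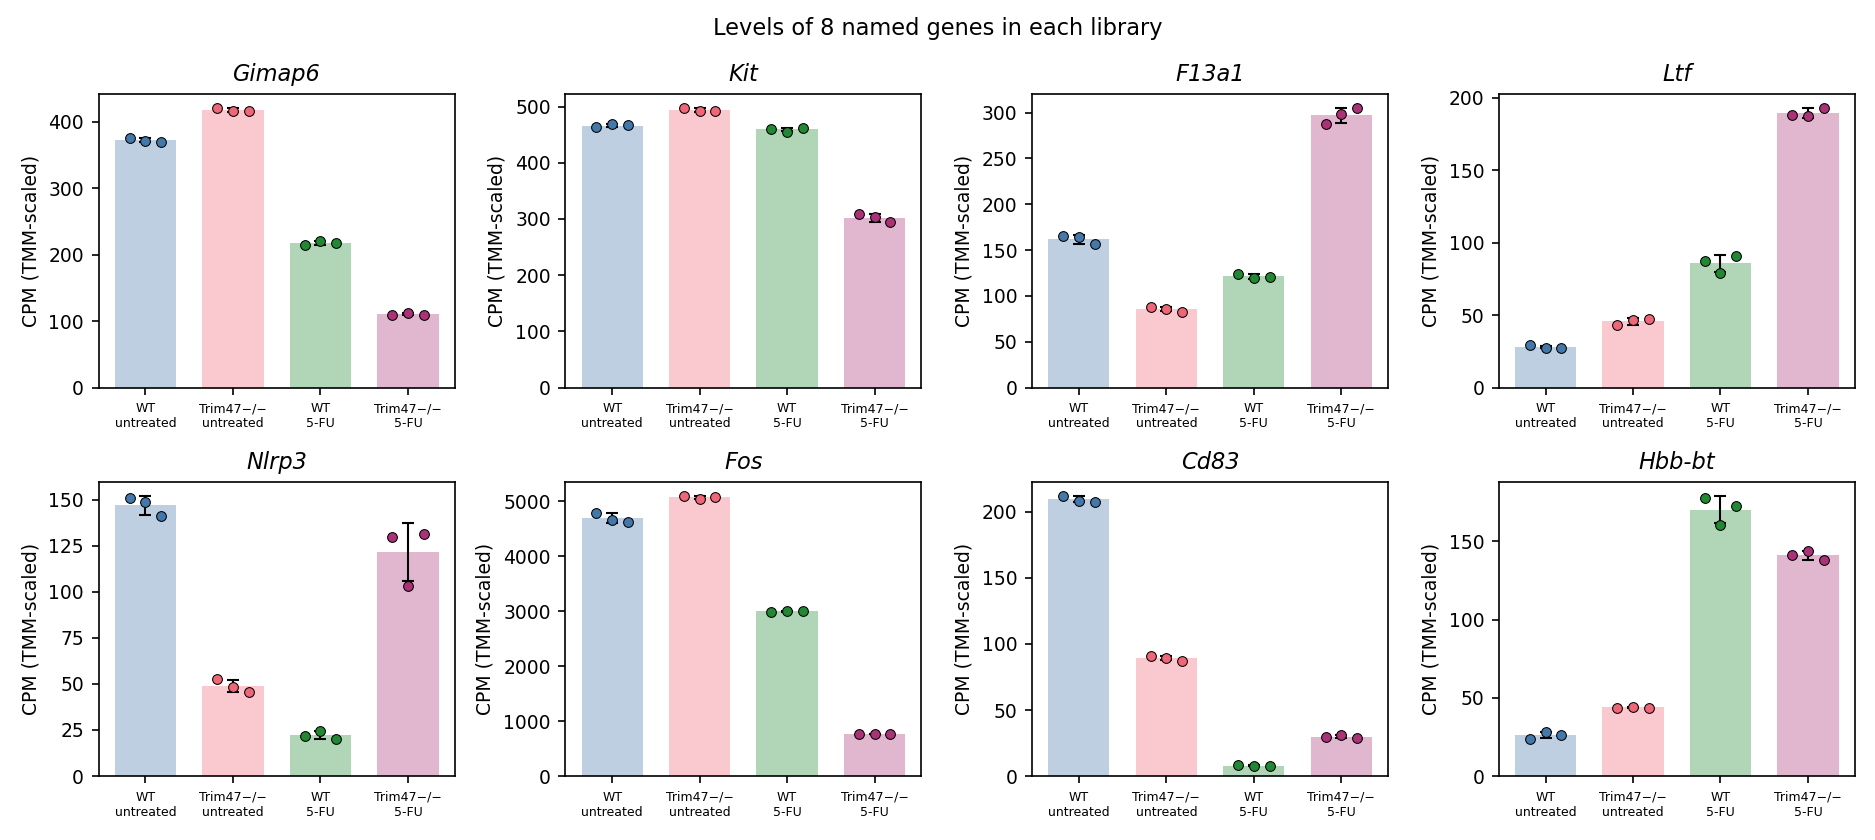
Levels of 8 named genes in TMM-scaled CPM (y axes, each from 0) by group (x axes), with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. Fos was lowest in Trim47-/- after 5-FU (768 CPM), and Nlrp3 was higher in untreated wild type (147 CPM) and in Trim47-/- after 5-FU (121 CPM) than in the other groups.

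In wild-type libraries labelled LT-HSCs, 5-FU was followed by lower NF-kB target, immediate early and B cell genes and by higher erythroid, neutrophil and megakaryocyte genes. Of 32 NF-kB targets, 2 rose, 28 fell and 2 did not pass (2 and 28 adjusted over the list alone), 22 by at least 2-fold (median -1.28, adjusted p = 2.06e-15). Cd83 went from 209 ± 2.29 CPM untreated to 7.97 ± 0.102 CPM after 5-FU (SD, n = 3 each), log2 -4.71 (SE 0.0385, adjusted p = 8.58e-15). Icam1, Cxcl2 and Nfkb2 changed by -2.29, -2.31 and -1.43. Of 30 immediate early genes, 1 rose, 27 fell and 2 did not pass (1 and 27 adjusted over the list alone, median -0.79, adjusted p = 1.24e-16). With an estimated correlation the immediate early list had adjusted p = 0.000659. Nr4a3 changed by -2.07 and Egr1 by -1.00. Other large falls were those of Acod1 (-3.51, SE 0.121), Arl5c (-3.22, SE 0.113), Egr4 (-2.98, SE 0.093) and the MAP kinase phosphatase Dusp8 (-2.85, SE 0.0914). Amd1 changed by -2.77 (SE 0.887, adjusted p = 0.0218). It lost its call without wild-type untreated replicate 1 or 3 (adjusted p = 0.0593 and 0.0617) and without each of the 3 libraries after 5-FU (0.0639, 0.0615 and 0.0566), with a range of 0.0047 to 0.0639 over its alternatives. The largest rise by this rule was in Lipg, endothelial lipase (0.738 ± 0.0406 to 24 ± 1.23 CPM, log2 5.01 (SE 0.17, adjusted p = 7.98e-10)). Col18a1, a basement membrane collagen, rose by 3.90 (SE 0.103), Clca3a1 by 3.11 (SE 0.0865) and the secreted glycoprotein Lrg1 by 2.47 (SE 0.135). The adult beta-globins Hbb-bt (2.71, SE 0.0547) and Hbb-bs (2.43, SE 0.0928), which can share reads, rose as well. In edgeR's test 8260 genes passed, 4110 higher and 4150 lower after 5-FU, and 1619 changed at least 2-fold (467 higher, 1152 lower). Among genes within 1.5-fold among replicates, a restriction chosen after seeing the data, the balance turned to 3564 higher and 3159 lower.

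In wild type after 5-FU, of 17 erythroid genes, 16 rose, 1 fell and 0 did not pass (16 and 1 adjusted over the list alone, median 1.61, adjusted p = 5.00e-09). Hba-a1 changed by 2.33 and Slc4a1 by 2.35. Of 18 neutrophil genes, 14 rose, 0 fell and 4 did not pass (15 and 0 adjusted over the list alone, median 0.47, adjusted p = 2.26e-08). Lcn2 rose by 2.05, Chil3 by 1.97 and S100a8 by 1.05. Of 16 megakaryocyte and platelet genes, 12 rose, 1 fell and 3 did not pass (12 and 1 adjusted over the list alone, median 0.57, adjusted p = 0.000156). They included Selp (2.31), Cd9 (1.28) and Vwf (1.13). Of 14 B cell genes, 1 rose, 12 fell and 1 did not pass (1 and 12 adjusted over the list alone, median -1.36, adjusted p = 0.000191). The kappa light chain constant gene Igkc went from 672 ± 8.79 to 216 ± 8.8 CPM. Of 12 dendritic cell genes, 1 rose, 9 fell and 2 did not pass (1 and 9 adjusted over the list alone, median -1.17, adjusted p = 0.0022), and Ccr7 changed by -2.29. Of 46 type I interferon response genes, 6 rose, 26 fell and 14 did not pass (6 and 26 adjusted over the list alone, median -0.29, adjusted p = 0.00202), and Gbp3 changed by -0.62. DNA replication and mitotic genes moved in opposite directions. Of 35 G1/S genes, 1 rose, 22 fell and 12 did not pass (2 and 22 adjusted over the list alone, median -0.18, adjusted p = 0.000212), and Pcna changed by -0.45. Of 35 G2/M genes, 22 rose, 5 fell and 8 did not pass (22 and 5 adjusted over the list alone, median 0.18, adjusted p = 0.00233), and Ccnb2, cyclin B2, rose by 0.74. Of 74 nuclear oxidative phosphorylation genes, 29 rose, 1 fell and 44 did not pass (28 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.000831), and Ndufv3 rose by 0.38. Of 25 unfolded protein response genes, 4 rose, 13 fell and 8 did not pass (4 and 13 adjusted over the list alone, median -0.14, adjusted p = 0.0076), but adjusted p = 0.0674 with an estimated correlation (0.0044 to 0.0674 over its alternatives). Ddit3 changed by -2.29 and Hspa5 by -0.75. A lower median than that of the unfolded protein response list was found in 6.48% of random lists. Of 13 mitochondrially encoded genes, 1 rose, 9 fell and 3 did not pass (1 and 10 adjusted over the list alone), mt-Nd2 by -0.23 (median -0.10, adjusted p = 0.0297). The list had adjusted p = 0.377 with an estimated correlation (0.0197 to 0.377 over its alternatives), and adjusted p = 0.0643 without 5-FU replicate 3. A lower median was found in 33.8% of random lists, so this list did not stand out by its median. As a share of all counts, mitochondrial messenger RNA rose from 2.42% to 2.49%. The direction of this list thus depended on how the libraries were scaled. LT-HSC identity genes went both ways, as 13 rose, 10 fell and 12 did not pass (13 and 10 adjusted over the list alone) of 35 (adjusted p = 0.547). Slamf1 (CD150) rose from 1.89 to 16.3 CPM, while Gimap6 (-0.78) and Tgm2 (-1.33) fell. In untreated wild type, Flt3 (711 CPM), Dntt (313 CPM) and Igha (1208 CPM of all counts) stood above Slamf1. Gimap6 and Kit of the LT-HSC list also stood above it. Other cells may thus have been in the sort. The immunoglobulin V segments together took 0.132% of counts in untreated wild type and 0.0444% after 5-FU (means, n = 3 each). In Trim47-/- they took 0.121% and 0.0304%. With the lower B cell genes, these values argue against an equal share of B-lineage cells in untreated and treated sorts. Whether the make-up of the sort differed in other cells was not tested.

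In libraries labelled Trim47-/-, 5-FU was followed by lower immediate early, LT-HSC, lymphoid and B cell genes and by higher oxidative phosphorylation, neutrophil, monocyte, megakaryocyte and erythroid genes. Of 30 immediate early genes, 1 rose, 29 fell and 0 did not pass (1 and 29 adjusted over the list alone), 20 by at least 2-fold (median -1.13, adjusted p = 4.65e-18). With an estimated correlation this list had adjusted p = 0.000889. Fos went from 5073 ± 26.7 to 768 ± 7.24 CPM (SD, n = 3 each), and Zfp36, Egr1 and Jun changed by -2.52, -2.28 and -1.71. Of 35 LT-HSC identity genes, 5 rose, 23 fell and 7 did not pass (5 and 23 adjusted over the list alone, median -0.63, adjusted p = 7.80e-05). Gimap6 changed by -1.93, Eya2 by -1.70 and Kit by -0.71. Cd69, an early activation marker of leukocytes, went from 1247 ± 10.6 to 166 ± 4.23 CPM, log2 -2.91 (SE 0.0194, adjusted p = 3.59e-16). The largest falls by this rule were in Obsl1 (-3.94, SE 0.147), Shisa8 (-3.50, SE 0.0779), Arpp21 (-3.02, SE 0.136), Gimap8 (-2.96, SE 0.0812) and the gelatinase Mmp2 (-2.93, SE 0.106). Lipg (3.89, SE 0.146) and Col18a1 (3.45, SE 0.0985) led the rises. They were followed by Emilin2 (2.68, SE 0.0687), Gas7 (2.60, SE 0.446), Mmp19 (2.58, SE 0.194) and the pseudogene Scp2-ps2 (2.42, SE 0.573). Over all 4 groups, replicates of Gas7 lay up to 3.62-fold apart and those of Scp2-ps2 up to 4.20-fold. In Trim47-/-, Scp2-ps2 stood at 7.41 ± 1.58 CPM untreated and 39.8 ± 3.42 CPM after 5-FU. In edgeR's test 9868 genes passed, 4837 higher and 5031 lower after 5-FU, and 2183 changed at least 2-fold (657 higher, 1526 lower). Here too the balance turned among genes within 1.5-fold among replicates (4206 and 3711).

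In libraries labelled Trim47-/- after 5-FU, of 74 nuclear oxidative phosphorylation genes, 68 rose, 0 fell and 6 did not pass (68 and 0 adjusted over the list alone, median 0.44, adjusted p = 1.11e-13). Atp5b rose by 0.49 and Ndufb7 by 0.72. Of 18 neutrophil genes, 16 rose, 1 fell and 1 did not pass (16 and 1 adjusted over the list alone, median 1.23, adjusted p = 1.88e-09), and Ctsg rose by 1.65. Of 15 monocyte and macrophage genes, 10 rose, 1 fell and 4 did not pass (10 and 1 adjusted over the list alone, median 1.25, adjusted p = 0.000873), and F13a1 went from 85.4 ± 2.3 to 297 ± 8.37 CPM. Of 16 megakaryocyte and platelet genes, 12 rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone, median 1.02, adjusted p = 5.08e-05), and Selp rose by 1.98. Of 17 erythroid genes, 13 rose, 2 fell and 2 did not pass (13 and 2 adjusted over the list alone, median 0.90, adjusted p = 0.00182). Hba-a1 rose by 1.38, whereas Car2 changed by -1.03. Of 14 B cell genes, 0 rose, 11 fell and 3 did not pass (0 and 11 adjusted over the list alone, median -1.94, adjusted p = 0.000198), and Igkc changed by -2.25. Of 15 multipotent progenitor and lymphoid genes, 2 rose, 11 fell and 2 did not pass (3 and 11 adjusted over the list alone, median -0.94, adjusted p = 0.00278), and Dntt changed by -1.18. Of 22 CDK inhibitors and quiescence regulators, 4 rose, 15 fell and 3 did not pass (4 and 15 adjusted over the list alone, median -0.59, adjusted p = 0.00278). Hes1 (-2.65) and Foxo3 (-0.71) fell. Of 37 DNA repair genes, 6 rose, 20 fell and 11 did not pass (6 and 20 adjusted over the list alone, median -0.23, adjusted p = 0.0242), and Xrcc5 changed by -1.09. Of 25 unfolded protein response genes, 17 rose, 5 fell and 3 did not pass (17 and 5 adjusted over the list alone, median 0.35, adjusted p = 0.00394). Pdia4 rose by 0.68, although Hspa5 (-0.67) and Ddit3 (-1.18) fell. Of 79 cytosolic ribosomal protein genes, 34 rose, 8 fell and 37 did not pass (33 and 6 adjusted over the list alone, median 0.10, adjusted p = 0.0187). A lower median was found in 61.5% of random lists, so this list did not stand out by its median. Rpl8 rose by 0.32 and Rpl22 changed by -0.30. Of 20 glycolysis genes, 12 rose, 5 fell and 3 did not pass (12 and 6 adjusted over the list alone, median 0.30, adjusted p = 0.0456). Slc2a3 (-0.87) fell and Ldha (0.73) rose. The list had adjusted p = 0.116 with an estimated correlation (0.0348 to 0.116 over its alternatives), 0.0513 with the replicate block, 0.0692 with only the 6 libraries compared and 0.0539 without untreated replicate 3. Of 32 NF-kB targets, 11 rose, 14 fell and 7 did not pass (11 and 14 adjusted over the list alone, camera adjusted p = 0.189).

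The effect of genotype ran in opposite directions in the untreated and treated states for most genes that passed in both. Of 3971 such genes, 3388 (85.3%) had opposite signs and 583 had the same sign. Genes higher in untreated Trim47-/- and lower in Trim47-/- after 5-FU numbered 1806, against 792.1 for independent lists (odds ratio 6.76). Genes lower and then higher numbered 1582, against 684.4 (odds ratio 6.48). Higher in both were 348 genes, against 780.6 (two-sided Fisher's exact p = 7e-101), and lower in both 235, against 694.5 (exact p = 2.47e-130). Among changes of at least 2-fold, the deficit of shared directions was not seen. There, 9 genes were higher in both, more than the 4.08 for independent lists (exact p = 0.0214), and 26 were lower in both, against 26.6 (exact p = 1). Opposite directions remained in excess there, with 172 genes lower and then higher (16.6 for independent lists) and 40 higher and then lower (6.55). Genes are not independent replicates, which limits these exact p-values as well as the correlations. Across genes the fold changes correlated at r = -0.261 and rho = -0.480. Of the 42 genes that the rule for largest changes and the target selected in the pairwise comparisons, 28 passed between genotypes in both states and 25 of these had opposite signs. Apart from Trim47, these genes were chosen for large changes in the same libraries, so they are no separate support.

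**Figure D3:**
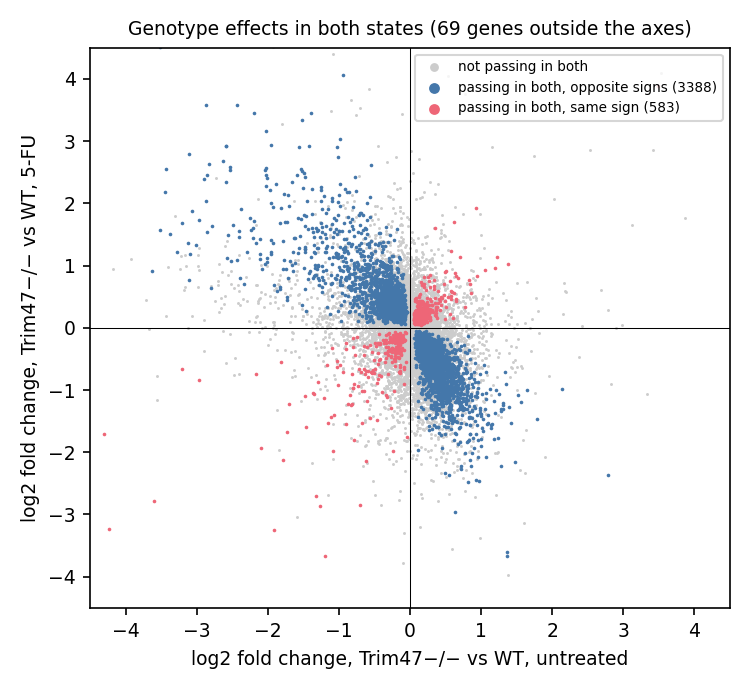
Log2 fold change of Trim47-/- against wild type in untreated mice (x axis) and after 5-FU (y axis), 1 point per gene, with 69 genes outside the axes of ±4.5. Of the genes that passed in both, 3388 with opposite signs (blue) fill the upper left and lower right and 583 with the same sign (red) the other quadrants.

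The response to 5-FU itself shared genes between genotypes. In both genotypes 1573 genes rose, against 1218 for independent lists (two-sided Fisher's exact p = 3.08e-43), and 1655 fell, against 1279 (exact p = 4.47e-47). Opposite directions were also found: 1321 genes fell in wild type and rose in Trim47-/-, against 1230 (odds ratio 1.15, exact p = 0.000367), and 1242 rose and fell, against 1267 (exact p = 0.329). Among changes of at least 2-fold, 129 rose in both (18.8 for independent lists), 401 fell in both (107.7), 122 fell and rose (46.4, exact p = 1.05e-23) and 26 rose and fell (43.7, exact p = 0.00355). Across genes the correlation was r = 0.263 and rho = 0.0994. Where the response differed was tested by the interaction. Of 32 NF-kB targets, 25 were more positive and 4 more negative (25 and 4 adjusted over the list alone) in libraries labelled Trim47-/- than in wild type (median 1.05, adjusted p = 9.68e-07). Of 35 LT-HSC identity genes, 3 were more positive and 28 more negative (3 and 28 adjusted over the list alone, median -1.15, adjusted p = 9.68e-07). Gimap6 stood at -1.15 (SE 0.0271) and Eya2 at -1.59 (SE 0.058). Acod1 had the largest positive interaction by the rule for named genes, 4.89 (SE 0.161, adjusted p = 8.02e-10). It went from 28.6 ± 1.19 to 2.51 ± 0.442 CPM in wild type and from 7.33 ± 0.742 to 19.2 ± 1.57 CPM in Trim47-/- (SD, n = 3 each). Nlrp3 (4.03, SE 0.136), Mmp19 (3.75, SE 0.277), the matrix glycoprotein gene Thbs1 (3.27, SE 0.0677), Lgals3 (3.21, SE 0.21) and Cd83 (3.14, SE 0.0496) followed. The largest negative interactions by this rule were in Gimap8 (-2.95, SE 0.108), Zfp532 (-2.64, SE 0.222), Eps8l1 (-2.55, SE 0.108), Zc3h6 (-2.55, SE 0.166), Gprc5b (-2.49, SE 0.121) and Ddx4 (-2.20, SE 0.125). In edgeR's test of the interaction 8957 genes passed, 4313 with a more positive and 4644 with a more negative response in Trim47-/-. Of these, 2774 differed at least 2-fold (1192 and 1582).

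Of 15 monocyte and macrophage genes, 11 were more positive and 0 more negative (11 and 0 adjusted over the list alone) in Trim47-/- (median 1.53, adjusted p = 0.000102), with F13a1 at 2.21. Of 12 dendritic cell genes, 9 were more positive and 1 more negative (9 and 1 adjusted over the list alone, median 1.41, adjusted p = 0.0147), with Bst2 at 1.41. Of 18 neutrophil genes, 13 were more positive and 3 more negative (13 and 3 adjusted over the list alone, median 0.33, adjusted p = 0.00681), with Ctsg at 1.31. Of 25 unfolded protein response genes, 20 were more positive and 1 more negative (20 and 1 adjusted over the list alone, median 0.66, adjusted p = 1.47e-06), with Calr at 0.73. Of 74 oxidative phosphorylation genes, 44 were more positive and 2 more negative (44 and 2 adjusted over the list alone, median 0.28, adjusted p = 8.96e-06), with Atp5b at 0.38. Of 35 G1/S genes, 20 were more positive and 0 more negative (20 and 0 adjusted over the list alone, median 0.19, adjusted p = 0.000186), with Mcm5 at 0.40. A lower median than that of the G1/S list was found in 90.8% of random lists. Of 79 ribosomal protein genes, 23 were more positive and 3 more negative (20 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.0235), with Rpl8 at 0.31. Only 32.1% of random lists had a lower median, so this median was not high for genes of such levels. Of 46 type I interferon response genes, 24 were more positive and 12 more negative (24 and 12 adjusted over the list alone, median 0.33, adjusted p = 0.0275). The list had adjusted p = 0.094 with an estimated correlation (0.0215 to 0.094 over its alternatives), and Irf7 stood at 1.55. Other lists had a more negative response in Trim47-/-. Of 17 erythroid genes, 1 was more positive and 15 more negative (1 and 15 adjusted over the list alone, median -0.92, adjusted p = 0.000144), with Hba-a1 at -0.95. Of 30 immediate early genes, 5 were more positive and 19 more negative (5 and 20 adjusted over the list alone, median -0.56, adjusted p = 1.18e-05), with Fos at -2.08. Of 12 endothelial and stromal genes, 0 were more positive and 7 more negative (0 and 8 adjusted over the list alone, median -0.96, adjusted p = 0.00746), with Emcn at -1.85. Of 22 CDK inhibitors and quiescence regulators, 3 were more positive and 14 more negative (4 and 14 adjusted over the list alone, median -0.31, adjusted p = 0.0225), with Gfi1 at -1.41. Of 15 multipotent progenitor and lymphoid genes, 3 were more positive and 10 more negative (3 and 11 adjusted over the list alone, median -0.57, adjusted p = 0.0225). The list had adjusted p = 0.052 with an estimated correlation (0.016 to 0.052 over its alternatives), and Dntt stood at -1.63.

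**Figure D4:**
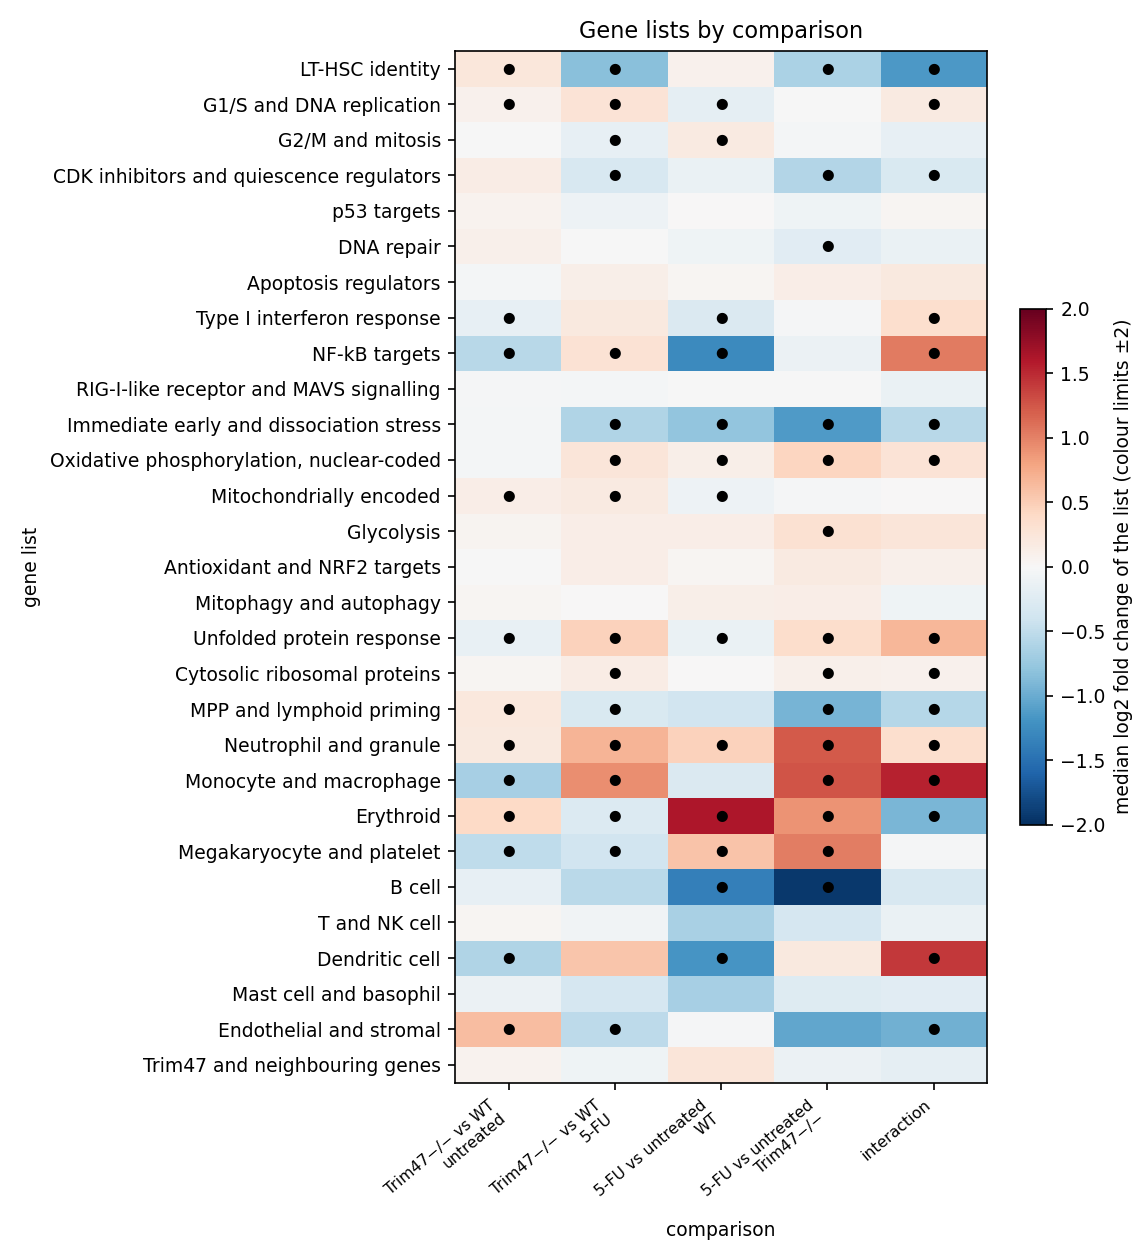
Median log2 fold change of each tested gene list (y axis, colour from -2 to 2) in each comparison (x axis), with a dot for an adjusted p under 0.05 in camera. The NF-kB list is lower in untreated Trim47-/- (-0.56) and in wild type after 5-FU (-1.28), and the LT-HSC list is lower in Trim47-/- after 5-FU (-0.84 against wild type).

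Some lists did not pass camera in any comparison. For RIG-I-like receptor and MAVS signalling, adjusted p-values were 0.438 between untreated genotypes, 0.676 after 5-FU, 0.56 for 5-FU in wild type, 0.984 in Trim47-/- and 0.978 for the interaction. Of its 29 genes, 7 rose and 9 fell (8 and 9 adjusted over the list alone) in untreated Trim47-/-, and after 5-FU 7 rose and 11 fell (7 and 11 adjusted over the list alone). Trim25, a ubiquitin ligase of that list, changed by -0.78 (SE 0.029) in untreated mice and rose by 0.59 (SE 0.0292) after 5-FU. For p53 targets the lowest adjusted p was 0.509, in untreated mice, where 10 rose and 3 fell (10 and 3 adjusted over the list alone) of 28. Pmaip1, the p53 target NOXA, changed there by -1.64 and rose by 1.44 after 5-FU. For apoptosis regulators it was 0.0966, in the interaction, where 12 were more positive and 5 more negative (12 and 5 adjusted over the list alone) of 28, with Birc3 at 1.29. For mitophagy and autophagy it was 0.0671, for 5-FU in wild type, where 15 rose and 5 fell (15 and 6 adjusted over the list alone) of 29, Ulk1 by -0.66. For antioxidant and NRF2 targets it was 0.0843, between genotypes after 5-FU, where 12 rose and 3 fell (12 and 3 adjusted over the list alone) of 26, with Gsr, glutathione reductase, at 0.47. T and NK cell genes came closest for 5-FU in wild type (adjusted p = 0.116), where 2 rose and 6 fell (2 and 6 adjusted over the list alone) of 12. So did mast cell and basophil genes (0.176), where 3 rose and 5 fell (3 and 5 adjusted over the list alone) of 11. Of 4 measured sex-linked genes, a list too short for camera, 1 rose and 1 fell (1 and 2 adjusted over the list alone) in untreated Trim47-/-. After 5-FU, 0 rose and 2 fell (0 and 2 adjusted over the list alone) in Trim47-/- against wild type, Uty at -0.68 (SE 0.0662, adjusted p = 5.43e-06) and Kdm5d at -0.40 (SE 0.0537, adjusted p = 7.65e-05). For 5-FU itself, 1 rose and 2 fell (1 and 2 adjusted over the list alone) in wild type, and 0 rose and 2 fell (0 and 3 adjusted over the list alone) in Trim47-/-.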

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

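The tests of V segments, of swapped labels, of single RNA pools and of other cell types were chosen only after the result was seen, unlike the interaction, the splits, the thinning of deep libraries and the comparison by number of transcripts.

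A difference between the responses of the 2 genotypes to 5-FU singled out 8957 genes that passed the interaction test in edgeR. Trim47 was among them, at a log2 difference of -1.34 (SE 0.167). Among genes that met the rule for named genes, the 6 largest more positive responses in libraries labelled Trim47-/- were in Acod1 (4.89), Nlrp3 (4.03), Mmp19 (3.75), Thbs1 (3.27), Lgals3 (3.21) and Cd83 (3.14), and the 6 largest more negative ones in Gimap8 (-2.95), Zfp532 (-2.64), Eps8l1 (-2.55), Zc3h6 (-2.55), Gprc5b (-2.49) and Ddx4 (-2.20). Of the 42 genes that the rule selected in the other comparisons, 39 passed the interaction test, against 54.9% of all 16319 genes tested. Apart from Trim47, the 42 were chosen for large changes in these same libraries, so this is no separate support. Among gene lists, camera gave adjusted p = 9.68e-07 for LT-HSC identity and for NF-kB targets, 1.47e-06 for the unfolded protein response, 8.96e-06 for oxidative phosphorylation and 1.18e-05 for immediate early genes. It gave 0.000102 for monocyte, 0.000144 for erythroid, 0.000186 for G1/S, 0.00681 for neutrophil, 0.00746 for endothelial and 0.0147 for dendritic cell genes. The CDK inhibitor and the multipotent progenitor lists stood at 0.0225, ribosomal proteins at 0.0235 and type I interferon genes at 0.0275. The ribosomal median lay above that of only 32.1% of random lists. With an estimated correlation the multipotent progenitor list (adjusted p = 0.052) and the type I interferon list (0.094) lost their calls, with ranges of 0.016 to 0.052 and 0.0215 to 0.094 over their alternatives. The real split of the libraries within treatments was set beside others drawn at random, 100 in all. Only the real one gave as many genes, and the highest other, which kept 1 treatment grouped by genotype, gave 5565. Of the kind that exchanges genotype labels in 1 treatment only, 0 splits were drawn. Libraries of a group share so much that mixing them lowers the count. The splits thus say nothing of other RNA pools and exclude no chance difference between them. The 80 splits that mixed both treatments gave at most 3.

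For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split, 1 of 10 in each, gave 5392 genes in untreated mice and the highest other 4; after 5-FU between genotypes 8933 and 1; for 5-FU in wild type 8260 and 3; and for 5-FU in Trim47-/- 9868 and 2.

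Libraries of a group differed by little more than counting noise in genes with 1 transcript and no overlapping gene, of which 2.40% to 4.35% lay beyond it where chance gives 1%, against 12.6% to 13.9% of all genes. Separate animals behind the libraries are argued against by the immunoglobulin V segments, whose lowest correlation within a group was 0.968 while the highest between groups, which include pairs of one genotype, was 0.699. A single RNA source per group, divided into libraries after the cells were collected, may account for both values. At matched counts, genes with 5 or more transcripts lay beyond counting noise at least 3.46 times as often as the genes with 1 transcript above. The latter had no overlapping gene, which was not required of the former, so transcript number and overlap were not told apart. Reads divided among overlapping transcripts by estimation may account for the difference. No biological explanation was tested for this pattern.

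Genotype effects ran opposite ways in untreated mice and after 5-FU. The deeper libraries of the untreated Trim47-/- group are argued against, since thinning them from a mean of 20681921 to 14848609 counts left rho at -0.474, from -0.480, with 5173 of 16292 genes passing in untreated mice. Swapped labels of the untreated groups could not be ruled out: Trim47 differed by -0.31 (SE 0.115) in log2 in the group labelled Trim47-/-, without passing the test. A difference between single RNA pools unrelated to genotype may also give 3388 genes with opposite signs, and other pools of the same groups would be needed to decide. An effect of genotype that depends on the state of the mice stays open, as untested.

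Libraries labelled Trim47-/- held lower LT-HSC genes and higher neutrophil and monocyte genes after 5-FU. A lower share of LT-HSCs that raises every other cell type alike could not be decided. The median megakaryocyte gene moved by -0.38 and the median erythroid gene by -0.27, while the median neutrophil gene moved by 0.67. Yet 15 of 16 megakaryocyte and 17 of 17 erythroid genes had at least 1 CPM in untreated wild type. If LT-HSCs use these genes, a lower share of LT-HSCs would lower them too. Neutrophils and monocytes carried into the sort could account for 14 of 18 neutrophil genes that rose. Between wild type and Trim47-/- after 5-FU, the abundant granule genes Mpo and S100a8 went from 1831 to 3285 CPM and from 223.9 to 287.6 CPM. Chil3 (-0.18) and Csf3r (-0.31) of that list fell. The gate of the sort is not given in the sources used here. A lower share of LT-HSCs, neutrophils and monocytes carried into the sort, and a change of the LT-HSCs themselves, which is untested, stay open.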

How the results depend on the processing

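The test against a 1.5-fold change, the restriction to genes within 1.5-fold among replicates, the summed libraries and the overlap of the 5-FU responses were chosen after seeing the data and the others were planned. Numbers stand in the order untreated genotypes, genotypes after 5-FU, 5-FU in wild type, 5-FU in Trim47-/- and interaction, where 5392, 8933, 8260, 9868 and 8957 genes passed. With a 2-fold threshold 612, 1434, 1619, 2183 and 2774 passed, in the 1.5-fold test 450, 1415, 1602, 2422 and 2913, and with libraries summed by group, without a test, 423, 1034, 1201, 1698 and 2392 genes changed at least 2-fold. An adjusted p under 0.01 left 3391 genes between untreated genotypes. Size factors, the DESeq2 test, no filter, the replicate block, a surrogate variable, the 6 libraries compared and the restricted genes moved no count by over 1.5 times; DESeq2 gave 4321, 8000, 7267, 9051 and 8082. The direction with more calls between untreated genotypes, 2873 higher against 2519 lower, turned with DESeq2 size factors (2567 and 2717), the DESeq2 test (1988 and 2333), the 6 libraries compared (2324 and 2712) and each stricter threshold. Between genotypes after 5-FU, 4434 against 4499, it turned with the replicate block (4384 and 4377), the surrogate variable (4242 and 4231), an adjusted p under 0.01 (3507 and 3417), the restricted genes (3926 and 3552) and without each library but wild-type replicate 3. For 5-FU it turned only in the restricted genes, from 4110 and 4150 to 3564 and 3159 in wild type and from 4837 and 5031 to 4206 and 3711 in Trim47-/-. Without 1 library, counts ran from 4551 to 4652, 8222 to 8270, 7522 to 7614, 9177 to 9271 and 8556 to 8684.

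Genes higher in both states numbered 348, against 9 with a 2-fold threshold, where they were more than for independent lists (4.08, exact p = 0.0214), and genes lower in both 235, against 26 (exact p = 1). Of 29 lists, camera called 13, 16, 13, 14 and 15; with an estimated correlation 7, 11, 11, 13 and 13; without 1 library 13 to 13, 16 to 17, 12 to 14, 13 to 15 and 15 to 15. Of named genes, Lrrc8d (adjusted p 0.0713) and Amd1 after 5-FU between genotypes (0.0504) and in wild type (0.0554) lost their calls without a filter, the last also with the surrogate variable (0.051). The cause was not tested. With DESeq2 size factors and with only the 6 libraries compared, 0 called lists had a median of the other sign.

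The replicate number does not pair the libraries: deviations of same-numbered libraries correlated at r = -0.104 to 0.086 across genes (18 pairs), those of different numbers at -0.070 to 0.096 (36 pairs), and in 0 libraries did each same-numbered partner correlate above all others. With the number as a block 5188, 8761, 8125, 9742 and 8827 genes passed, and the glycolysis list for 5-FU in Trim47-/- had adjusted p = 0.0513; no other list or named gene lost its call. A pseudocount was not varied since counts were tested. The depth limits genes under 0.145 to 0.216 CPM.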

Other observations

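The genes and tests of this part were chosen only after the result was seen. The immunoglobulin genes Igha and Igkc, the gene Jchain and the sum of the V segments were lower after 5-FU in both genotypes, though not every single segment was. Igha, the constant gene of IgA, stood at 1208 ± 8.19 CPM of all counts in untreated wild type, 1104 ± 27.9 in untreated Trim47-/-, 390.9 ± 26.0 in wild type after 5-FU and 281.4 ± 6.14 in Trim47-/- after 5-FU (SD, n = 3 each). Igkc, of the kappa light chain, stood at 654.3 ± 8.82, 662.4 ± 7.19, 226.1 ± 9.37 and 139.7 ± 4.30 CPM in the same order, and Jchain, which joins secreted antibodies, at 354.7 ± 3.35, 289.9 ± 104, 81.6 ± 30.5 and 52.5 ± 20.4 CPM.

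The V segments together took 0.132%, 0.121%, 0.0444% and 0.0304% of counts. Ighv3-8 (chromosome 12, 114322327 to 114322801 of GRCm38) had 43, 51 and 47 counts in untreated wild type, 312, 307 and 304 in untreated Trim47-/-, 1, 0 and 0 in wild type after 5-FU and 8, 12 and 18 in Trim47-/- after 5-FU. Igkv10-96 had 335, 327 and 343, then 808, 839 and 855, then 301, 322 and 281, then 47, 53 and 41 counts in that order, so it fell little in wild type. Igkv6-25 had 296, 264 and 290, then 832, 815 and 810, then 58, 60 and 57, then 32, 62 and 54 counts. Within groups, the 138, 140, 97 and 78 segments with enough counts had a median chi-square per degree of freedom of 0.672, 0.654, 0.649 and 0.928.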
